A study of Ocimum basilicum
Peronospora belbahrii and Ocimum basilicum and Peronospora belbahrii with 33 samples.

How the data were processed

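Polyadenylated RNA from basil leaf discs was sequenced in 30 libraries of 2 basil cultivars, Mirihani (MRI) and SB22, and RNA from sporangia of the downy mildew oomycete Peronospora belbahrii in 3 further samples. Plants at the 6-leaf stage were sprayed with a suspension of sporangia or with sterile water and kept in saturated humidity, per the labels' protocols. Leaves of each cultivar were taken 12, 24, 48 and 72 hours post inoculation (hpi) and, as mock, 12 hours after water, which gave 5 groups of 3 libraries per cultivar. The extraction text of the labels lists 12, 24 and 72 hpi and leaves out 48 hpi, whereas the sample titles and the series design give all 4 times. The groups followed the titles.

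Each deposited leaf table held expected counts, TPM and FPKM per feature, per the file headers, with feature identifiers of the form that transcriptome assemblers give to assembled components. Expected counts are estimates that divide reads shared between related features, and Bowtie 1.0.0 and RSEM 1.2.29 are named in the submitters' processing notes, with no role or order. TPM in the deposited tables, per the file headers, is scaled to the length of each feature and to 1 library at a time; it served for 1 alternative, and the FPKM of the authors was not used. How the assemblies were built, which reads entered them and whether replicates were pooled is not given in the sources used here. The list of MRI held 133441 features, that of SB22 118296 features and that of the sporangia 10142 features. Of the 43402 identifiers present in both leaf lists, 0.198% belonged to features whose lengths differed by less than 1 base, so no feature was joined across lists. The same held for the 1454 and 1049 identifiers that the sporangia list had in common with MRI and SB22. The files do not pair the identifiers with gene names, so the gene lists written before the data were examined were not usable. The planned test of a cultivar-by-infection interaction per feature was not run, since it needed 1 list for both cultivars. The authors deposited 1 table for the 3 sporangia samples; it is given as their value, with no SD.

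Total expected counts per leaf library ran from 6504048 to 21283206. Mock libraries were shallower than inoculated ones. They held 7868797 to 10135334 counts in MRI and 6504048 to 10772335 in SB22. Inoculated libraries held 11007732 to 19560953 and 13988289 to 21283206. In each library at least 99.89% of the values were whole numbers at the 2 decimals deposited. In none of the 30 pairs of replicates were the tables identical, and a chi-square of the counts over features with at least 100 counts in the pair gave 5.67 to 177 per degree of freedom, so all replicates were counted separately. Intervals and floors stated for counts cover counting error only, since reads without molecular identifiers are not independent molecules.

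Expected counts were rounded to whole numbers and tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with TMM normalization and default expression filtering, in 1 fit of the 15 libraries per cultivar. The filter left 32026 features in MRI and 33975 in SB22. Each time was compared with mock and with the time before it, and a feature counted as changed at a Benjamini-Hochberg adjusted p below 0.05. Standard errors were derived from the log2 fold change and its F statistic. Features were named by a rule fixed in advance: the 2 largest rises and the 2 largest falls per cultivar at 72 hpi against mock. They were taken among changed features with at least 10 CPM in the higher group and no overlap between the groups. CPM are the rounded counts scaled to the library total. A fold against a group with no counts was taken against a floor of 3 counts per library and is a lower bound.

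RNA absent from mock leaves was measured as the percent of a library's expected counts that fell on features without a count in the mock libraries of the same cultivar. A mock library was scored with the features that had no count in the other 2 mock libraries. An inoculated library was scored with the mean over the 3 such definitions, so that both kinds rest on like definitions. For this share, mock-undetected thus means no count in 2 of the 3 mock libraries. Elsewhere it means no count in any of the 3. The plan preferred identifiers of the sporangia table for this purpose, but the lists could not be joined. Log2 shares were compared by exact permutation tests for 3 against 3 libraries, by 100000 permutations of the time labels for 72 against 12 hpi, and by exact permutation of the cultivar labels within times. All tests were two-sided, and adjusted values cover the family of 13 tests of this share.

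The edgeR step was tested on simulated counts for the real features, with 200 features changed at 72 hpi. The changed features were drawn only from well-covered ones, by a minimum mean count. For MRI 72 hpi against mock, on 30554 features, 35% of the features changed 2-fold and 91% of those changed 4-fold were recovered, with 3 false calls. For SB22 72 hpi against mock, on 32311 features, the values were 38%, 77% and 10 false calls. With no change simulated, 12 hpi against mock gave 0 false calls in MRI and 2 in SB22. In simulated SB22 libraries of 72 hpi with 5% of added counts, the share over the list of 118296 features came out at 5.05%. The added counts lay on features without a count in any mock library, so this outcome was fixed by construction. It checks the calculation alone. The draws held counting error only, and simulated mock libraries had a share of 0.0472%, against 0.0841% in the real ones.

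Alternatives fixed before the data were examined were DESeq2 1.42.0, its size factors within edgeR, no expression filter and a filter of 1 CPM in 3 libraries. Others were fits of the 2 groups alone, a replicate block, a fold of at least 1.5 tested with glmTreat and removal of mock-undetected features. The share was recomputed with TPM and with 2 other definitions, and each replicate was left out in turn. Thinning of all libraries to 1 total and further changes to the share were added after the data were seen. Replicate numbers were checked for pairing through the correlation of deviations from group means: all 3 correlations passed 0.1 only for MRI 48 against 24 hpi (0.493, 0.776 and 0.153). The replicate numbers were therefore taken to pair the libraries of that contrast alone. This pairing is uncertain, since not every 48 hpi library there correlated best with the 24 hpi library of its own number. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used for the remaining steps.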

Results

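Leaves of 2 basil cultivars were followed through inoculation with Peronospora belbahrii, the oomycete that causes basil downy mildew. Each cultivar, MRI and SB22, had 3 libraries at each of 12, 24, 48 and 72 hpi and 3 mock libraries from water-sprayed leaves taken at 12 hours, 30 leaf libraries in all. MRI is known as a cultivar resistant to the disease and SB22 as a susceptible breeding line. Depth ran from 6504048 to 21283206 expected counts per library, and the mock libraries were the shallowest groups. A further table covered 3 samples of sporangia, which the labels call the pathogen control. The labels do not say whether replicates came from separate plants, so p-values measured the spread between these samples, which may be partly technical.

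Along the first principal component the MRI libraries fell into an early and a late set. Those of SB22 were spread out along it in the order mock, 12 hpi, then 24 with 48 hpi, then 72 hpi. The first principal component held 30.4% of the variance in MRI and 67.7% in SB22. Along it, all mock and 12 hpi libraries lay below all libraries of 24, 48 and 72 hpi. The second component of MRI held 24.9% of the variance and parted mock (29.5 to 137) from 12 hpi (-99.1 to -63.9). It also set 72 hpi replicate 3 (54.8) apart from replicates 1 and 2 (-98.4 and -75.2). The 100 most abundant features took 20.5% ± 2.72 of the counts in MRI mock and 18.7% ± 1.06 at 12 hpi, but 13.7% ± 1.18 at 24 hpi, 14.3% ± 0.317 at 48 hpi and 14.9% ± 1.5 at 72 hpi (SD, n = 3 each). In SB22 the same share was 24.9% ± 0.504 in mock, 25.7% ± 1.09 at 12 hpi, 16.8% ± 0.295 at 24 hpi, 16.8% ± 0.310 at 48 hpi and 16.0% ± 1.39 at 72 hpi (SD, n = 3 each). The groups differed by more than the spread between replicates in MRI (permutation test, p = 0.00154) and in SB22 (permutation test, p = 0.00087).

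**Figure D1:**
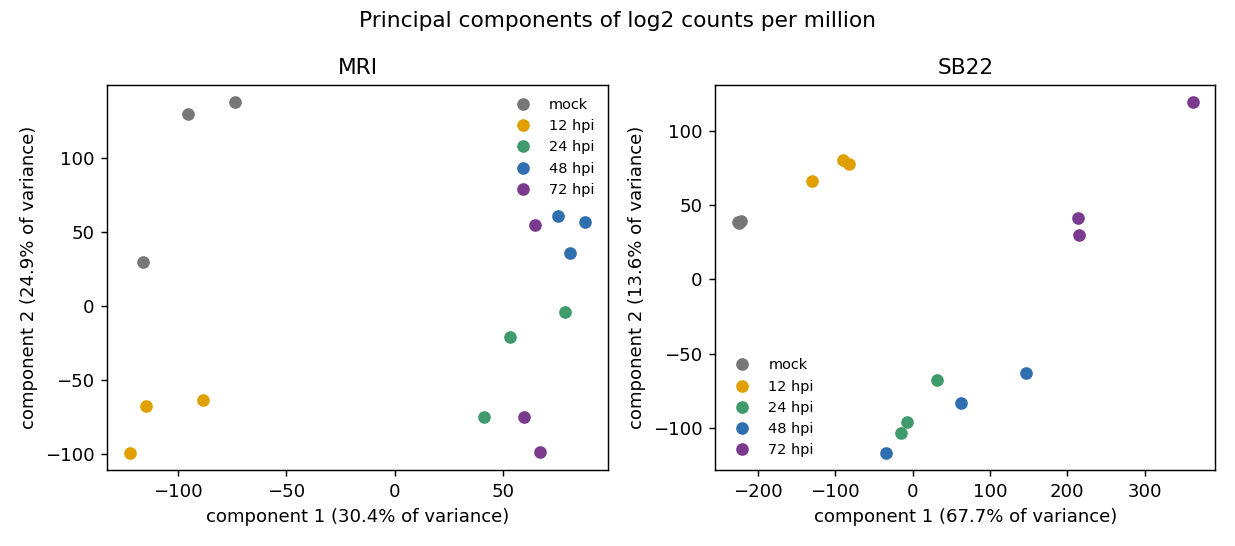
First 2 principal components of log2 CPM for MRI (left) and SB22 (right); each point is a library, coloured by group, and the axis titles give the percent of variance. Mock and 12 hpi libraries lie to the left of the 24, 48 and 72 hpi libraries along component 1, which held 30.4% of the variance in MRI and 67.7% in SB22.

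The share of counts on features without a count in 2 mock libraries was used to ask how much RNA appeared that mock leaves lacked. Mock leaves were taken at 12 hours alone, so leaf RNA that appears with time after spraying or time of day would also count. A mock library was scored with the other 2, and an inoculated library with the mean over the 3 choices of 2. The mock library left out can hold counts on these features. In SB22 this share rose along the time course, from 0.422% ± 0.319 at 12 hpi to 0.609% ± 0.113 at 24 hpi, 1.63% ± 1.07 at 48 hpi and 10.8% ± 9.30 at 72 hpi (SD, n = 3 each), against 0.0841% ± 0.0151 in mock. In MRI it reached at most 1.17% in an inoculated library, with 0.703% ± 0.407 at 12 hpi, 0.493% ± 0.165 at 24 hpi, 0.376% ± 0.243 at 48 hpi and 0.668% ± 0.336 at 72 hpi (SD, n = 3 each), against 0.284% ± 0.192 in mock. The MRI mock libraries ranged from 0.0625% to 0.401%. At 12 hpi in SB22, replicate 2 held 0.788% and the others 0.200% and 0.280%. At 48 hpi replicate 2 was again the highest, with 2.87% in SB22 (others 0.927% and 1.10%) and 0.655% in MRI (others 0.252% and 0.220%). The SB22 libraries of 72 hpi ranged from 5.45% to 21.6%, the highest value being that of replicate 3. Counting error was small beside this, the widest 95% Wilson interval of a library being 0.0374 percentage points.

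From 12 to 72 hpi the share of SB22 rose 24.5-fold in the geometric mean (log2 difference 4.61, permutation test, p = 0.00037, adjusted p = 0.00481), with each of the 3 late libraries above each of the 3 early ones. The permutations shuffled all 12 inoculated libraries, those of 24 and 48 hpi included. An exact test of 72 against 12 hpi alone, 3 against 3 libraries, could not go below p = 0.1. The log2 difference was 3.95 without 72 hpi replicate 3 and 2.25 with TPM in place of counts. That of MRI differed by a log2 of -0.05 (permutation test, p = 0.947, adjusted p = 0.947). Its sign turned when 12 hpi replicate 1 (0.40), 72 hpi replicate 2 (0.00) or 72 hpi replicate 3 (0.29) was left out. The 2 changes differed by a log2 of 4.66 (exact permutation test, p = 0.02, adjusted p = 0.065). The permutations assume no cultivar difference at either time, so they do not test the changes apart from an offset between the cultivars. Over the 4 times SB22 lay 2.56-fold above MRI (log2 difference 1.35, exact permutation test, p = 0.0155, adjusted p = 0.065). This comparison rests on separate feature lists and lost its raw significance without replicate 1, 2 or 3 (log2 1.46, 0.92 and 0.99) and with TPM (log2 0.51, exact permutation test, p = 0.0958). By time the ratio of geometric means, SB22 over MRI, was 0.557 at 12 hpi, 1.26 at 24 hpi, 4.32 at 48 hpi and 14.1 at 72 hpi, with exact permutation p-values of 0.4, 0.3, 0.1 and 0.1. Against mock, every inoculated group of SB22 and the 12 hpi group of MRI reached p = 0.1 in the exact test, which is the smallest that 3 against 3 libraries can give. MRI at 24, 48 and 72 hpi gave 0.3, 0.7 and 0.3.

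**Figure D2:**
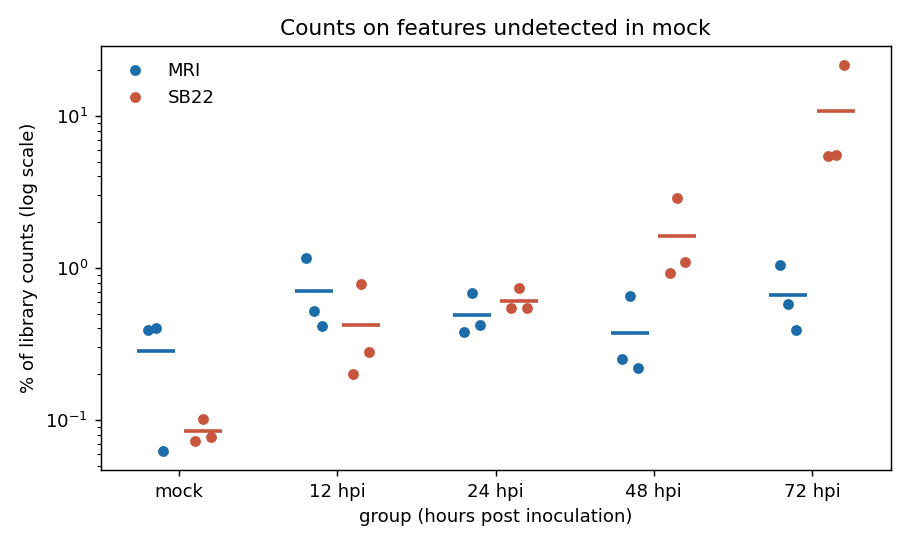
Percent of each library's expected counts on features without a count in mock (log axis) by group, with a point per library and a bar at each mean of 3 libraries, MRI in blue and SB22 in red. The SB22 libraries of 72 hpi lie between 5.45% and 21.6%, above all MRI libraries, while the MRI group means stay between 0.284% and 0.703%.

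At 12 hpi, the only time with a mock of the same age, few features differed from mock, and in MRI nearly all of them were higher. Of 32026 features tested in MRI, 314 rose and 5 fell. Among the 314, 211 (67.2%) had no count in any mock library, against 1719 of the 32026 tested. The other 103 rose by a median log2 of 6.21. A single count in 1 mock library was enough to be among these, so this median can rest on mock levels near 0. With the 211 set to a floor of 3 counts per mock library, the median of all 314 was a log2 of 3.42. In SB22, 158 of 33975 features rose and 95 fell. Of the 158, 18 lacked counts in mock, against 4767 of the 33975 tested. The other 140 rose by a median log2 of 0.83, while the 95 fell by a median log2 of 1.02.

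These 12 hpi counts come from the quasi-likelihood test of edgeR at an adjusted p below 0.05. Leaving out 1 library moved them by over 1.5 times: the 319 features of MRI became 28, 96 or 25 without mock replicate 1, 2 or 3 and 60 or 63 without 12 hpi replicate 1 or 2, and the 253 of SB22 fell to between 58 and 108 without any one of its 6 libraries. DESeq2 called 1494 and 2382. In MRI no expression filter gave 2776, and a fit without the mock-undetected features called 31, all higher, where 103 detected features had risen and 5 had fallen. The balance in SB22 was not stable either: higher features made up 62.5% of the calls, but 52.2% with the size factors of DESeq2, 76.6% with DESeq2, 83.5% with no expression filter and 85.8% with a filter of 1 CPM. Without mock replicate 2 or 3 more features fell than rose (59 against 47 and 33 against 25).

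At 24, 48 and 72 hpi many features differed from mock in both directions. In MRI 4528 features rose and 4363 fell at 24 hpi, 4527 rose and 4676 fell at 48 hpi, and 4834 rose and 4173 fell at 72 hpi. In SB22 7054 rose and 5804 fell at 24 hpi, 9857 rose and 6802 fell at 48 hpi, and 9310 rose and 6758 fell at 72 hpi. Features without counts in mock made up 26.4% of the MRI features that rose at 72 hpi (1274) and 45.6% of those in SB22 (4243). Such features can rise but not fall against mock, and they were 1719 of the 32026 tested in MRI and 4767 of the 33975 in SB22. Among features with a count in at least 1 mock library, the rises at 72 hpi had a median log2 of 1.05 in MRI and 1.2 in SB22. The falls had medians of -1.33 and -1.05.

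Because mock was taken at 12 hours alone, these contrasts hold the time after spraying, and the time of day, together with infection. The median log2 of all tested features in SB22 lay at 0.11 at 12 hpi, 0.18 at 24 hpi, 0.24 at 48 hpi and 0.08 at 72 hpi against mock. With mock-undetected features, which can only rise, left out, it lay at 0.04, 0.06, 0.09 and 0.04. Changes there are relative to these medians. The MRI count at 72 hpi fell from 9007 to 5939 without mock replicate 3 and to 5996 without 72 hpi replicate 1, and fits of the 2 groups alone gave 4834 at 24 hpi and 4652 at 72 hpi. Which direction held more MRI features depended on the setting: more fell than rose in those 2 fits (2741 against 2093 and 2608 against 2044) and with mock-undetected features left out (4286 against 3655 and 4037 against 3482). The same held without mock replicate 1 (3519 against 2834 and 3140 against 2868) and, at 24 hpi, without mock replicate 3 (3489 against 3217) or 24 hpi replicate 1, 2 or 3 (4203 against 3960, 3343 against 3260 and 3648 against 3603). At 48 hpi more rose than fell with no filter (4356 against 3750), and in SB22 at 24 hpi more fell than rose without mock replicate 2 (5355 against 5114). A tested fold of at least 1.5 also turned the 24 hpi balance in MRI (2387 lower against 1827) and SB22 (3228 against 3032), and thinning to equal depth that of MRI (3917 against 3803).

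**Figure D3:**
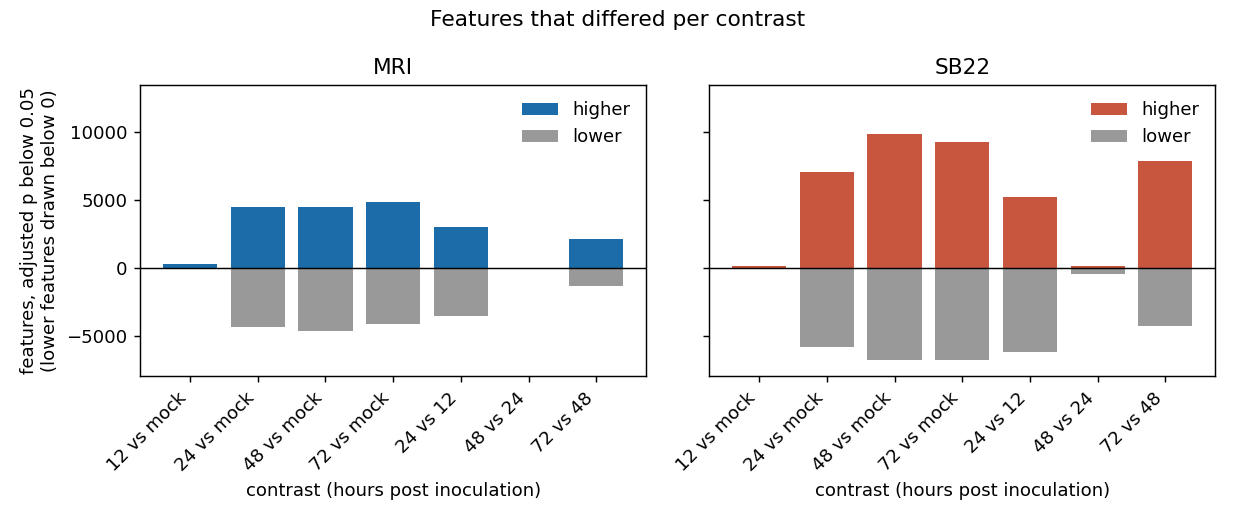
Number of features with an adjusted p below 0.05 in each contrast for MRI (left) and SB22 (right), with features higher in the later or inoculated group drawn upward and lower ones downward from 0 (edgeR, 3 libraries per group). The steps from 24 to 48 hpi, with 2 features in MRI and 550 in SB22, are small beside those from 12 to 24 hpi, with 6580 and 11436.

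The steps between neighbouring times, which use no mock library, were uneven in both cultivars. From 12 to 24 hpi 3024 features rose and 3556 fell in MRI, and 5211 rose and 6225 fell in SB22. From 24 to 48 hpi 1 feature rose and 1 fell in MRI, and 128 rose and 422 fell in SB22. From 48 to 72 hpi 2115 rose and 1359 fell in MRI, whereas 7902 rose and 4293 fell in SB22. Of these 7902, 3984 (50.4%) had no count in mock, against 4767 of the 33975 features tested. The median rise was a log2 of 3.55 among these 3984 and 1.37 among the other 3918 (1.35 with features at 0 at 48 hpi set to their bound), and the median fall was -0.64.

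The small count from 24 to 48 hpi in MRI stood beside 4143 features at an unadjusted p below 0.05, where 1601 would pass by chance, and beside 470 with DESeq2. With a replicate block over all 15 MRI libraries it was 1. That block set the same effect of a replicate number on all 5 groups, though only this contrast was taken as paired. A paired fit of the 24 and 48 hpi libraries alone was not run, so the count under pairing is not known. It was 320 without 24 hpi replicate 1, 1 without replicate 2 or 3 of 24 hpi and 0 without any one 48 hpi library. The SB22 count for this step was 283 or 82 without 24 hpi replicate 1 or 3 and 62 or 256 without 48 hpi replicate 2 or 3. DESeq2 gave 1227 higher and 1413 lower, no filter 452 and 533, and the fit without mock-undetected features 293 and 700. From 48 to 72 hpi the 3474 features of MRI became 724, 2100 or 735 without 48 hpi replicate 1, 2 or 3 and 1437 or 1064 without 72 hpi replicate 1 or 2. The 12195 of SB22 became 5574 without 48 hpi replicate 3 and 6497 without 72 hpi replicate 3. A fit of the 2 groups alone called 3578 features, of which more were lower (2046) than higher (1532), and with the size factors of DESeq2 8825 rose and 2997 fell.

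The named features with the largest falls at 72 hpi stayed under 1 CPM in every library from 24 hpi on, in both cultivars. Levels are given as CPM, counts scaled to the library total. In SB22, comp152515_c0 stood at 602 CPM ± 32.7 in mock and 644 ± 4.19 at 12 hpi, but at 0.0175 ± 0.0303 at 24 hpi and 0.527 ± 0.263 at 72 hpi (SD, n = 3 each; log2 fold change at 72 hpi -10.37 ± 0.30 SE, adjusted p = 5.32e-10 in edgeR). There comp149466_c0 went from 73.4 CPM ± 2.83 in mock and 73.2 ± 16.6 at 12 hpi to 0 in all 6 libraries of 24 and 48 hpi and 0.0829 ± 0.0737 at 72 hpi (log2 -9.87 ± 0.39 SE, adjusted p = 3.07e-07 in edgeR). In MRI, comp165414_c0 fell from 276 CPM ± 110 in mock and 241 ± 29.3 at 12 hpi to 0.019 ± 0.0329 at 24 hpi and 0.157 ± 0.0836 at 72 hpi (log2 -10.98 ± 0.60 SE, adjusted p = 2.16e-07 in edgeR). There comp178444_c1 went from 248 CPM ± 29.6 in mock and 199 ± 10.4 at 12 hpi to 0.0821 ± 0.0276 at 24 hpi and 0.153 ± 0.0896 at 72 hpi (log2 -10.81 ± 0.37 SE, adjusted p = 8.65e-09 in edgeR).

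The largest rises at 72 hpi were in features without a count in any mock library. In SB22, comp149328_c0 had 0.674 CPM ± 0.412 at 12 hpi, 1.34 ± 1.19 at 24 hpi, 73.5 ± 75.6 at 48 hpi and 841 ± 765 at 72 hpi (SD, n = 3 each), at least 2181-fold above mock (adjusted p = 0.000237 in edgeR). A second SB22 feature, comp153621_c1, reached 689 CPM ± 632 at 72 hpi, at least 1787-fold above mock (adjusted p = 0.00023 in edgeR). Replicates 1, 2 and 3 of 72 hpi held 434, 365 and 1723 CPM of the former and 341, 307 and 1418 CPM of the latter, and without replicate 3 the bounds were 1036-fold and 841-fold. In MRI, comp179456_c0 had 4.59 CPM ± 1.88 at 12 hpi, 3.91 ± 0.901 at 24 hpi, 0.904 ± 0.38 at 48 hpi and 42.9 ± 44.1 at 72 hpi, at least 125-fold above mock (adjusted p = 0.0047 in edgeR). The second, comp176661_c0, reached 35.4 CPM ± 38.6 at 72 hpi, at least 103-fold (adjusted p = 0.00822 in edgeR). The 3 MRI libraries of 72 hpi were far apart, with 88.5, 39.8 and 0.451 CPM for comp179456_c0 and 76.7, 29.4 and 0.169 CPM for comp176661_c0 in replicates 1, 2 and 3. Without replicate 1 the bounds were 58.9-fold and 43.2-fold. The floor behind these MRI bounds was 0.342 CPM. Replicate 3 lay little above it for comp179456_c0 and below it for comp176661_c0, so the bounds hold for the means and not for each library. Related components of an assembly can share reads, which the expected counts divide by estimate. The identifiers carry no name or sequence here, so neither the gene nor the organism behind these 8 features is given.

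**Figure D4:**
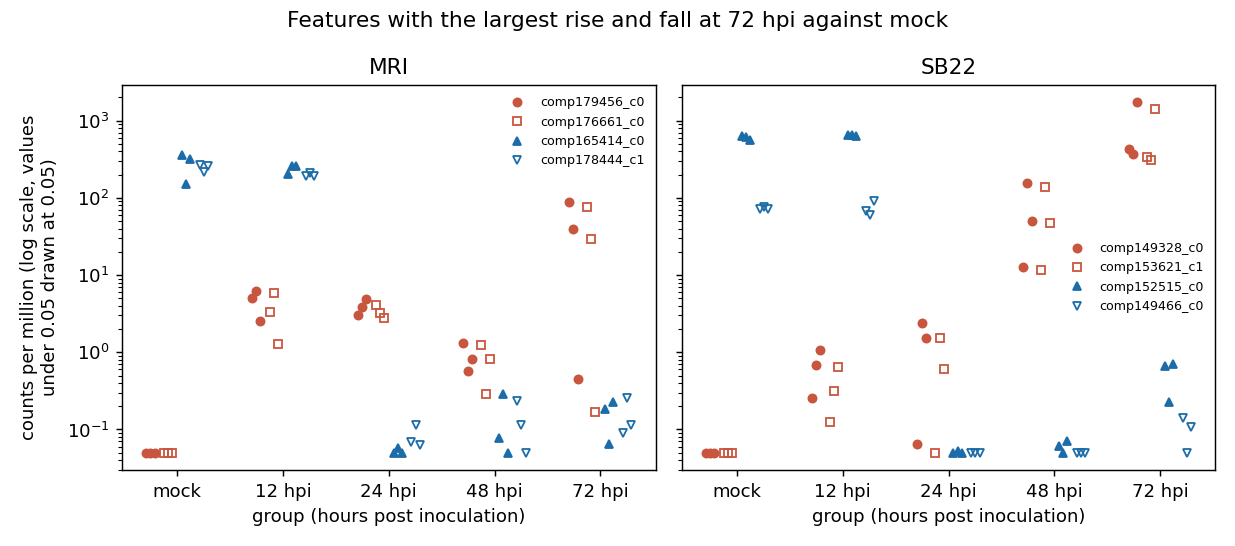
CPM, counts scaled to the library total (log axis, values under 0.05 drawn at 0.05) of the features with the largest rise (red) and fall (blue) at 72 hpi against mock, with 1 point per library, for MRI (left) and SB22 (right). The falling features stay near their mock level at 12 hpi and lie under 1 CPM from 24 hpi on, and the rising features have no count in mock.

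The table for the 3 sporangia samples held 26523261 expected counts on 10142 features, of which 9785 had a count. Its 100 most abundant features took 27.1% of the counts and the most abundant one 4.74%. It entered no comparison with the leaves, since its identifiers do not name the same features.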

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

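The values on the share are given a closer look because the cultivars differed under the same contrast, and the tests of explanations for them were all chosen after the result was seen. The change of the share of counts on mock-undetected features from 12 to 72 hpi was larger in SB22 than in MRI by a log2 of 4.66 (exact permutation test, p = 0.02, adjusted p = 0.065). The change from mock to 72 hpi was larger by a log2 of 5.17 (exact permutation test, p = 0.02, adjusted p = 0.065). All 3 SB22 libraries of 72 hpi lay above all 3 of MRI, and neither test passed the correction over 13 tests. Both tests assume no cultivar difference at either end of the change, so they do not part it from an offset between the cultivars. The shallow mock libraries do not account for the SB22 rise: with every SB22 library thinned to 6504048 counts, 3985 features had at least 5 counts in all 3 libraries of 72 hpi and none in mock, against 24 with the converse. A single added source of RNA, in amounts that differ between libraries, is a candidate explanation. Over the 3057 features with no count in mock and at least 5 CPM at 72 hpi, the log2 ratio of 72 hpi replicate 3 to the mean of the others had a median of 2.08, as its higher share implies, but its interquartile range of 0.27 (0.36 over features detected in mock, with a median of -0.32) could have been wider, and of 2089 features chosen without replicate 3, 97.8% were higher in it. Growth of the pathogen in the leaf would be such a source, and a joint response of leaf genes would move alike, but neither was tested, because neither list can be tied to the sporangia table. As mock leaves were taken at 12 hours alone, leaf RNA that appears with time after spraying could not be told apart either. Whether the cultivars differ in that amount cannot be told apart from a difference between their feature lists, which could not be joined (0.198% of the identifiers in both had equal length), and the cultivar difference in susceptibility stays open and untested.

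The sporangia table lay outside every comparison and held counts on 9785 features, with no control sample to set them against.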

How the results depend on the processing

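Thinning of libraries, the replicate block on the share and the restriction to features with a count in all 3 libraries of an inoculated time were chosen after seeing the data. The size factors of DESeq2 left all 14 contrast counts within 1.5 times. With DESeq2, 9 of 14 stayed so. The others were MRI 12 hpi against mock 1494, MRI 48 against 24 hpi 470, MRI 72 against 48 hpi 5774, SB22 12 hpi against mock 2382 and SB22 48 against 24 hpi 2640. No filter gave 2776, 809, 5630, 618 and 985 for the same contrasts. The filter of 1 CPM gave 839 for SB22 12 hpi against mock. Fits of the 2 groups alone gave 802 (MRI 12 hpi against mock), 4834 (MRI 24 hpi against mock), 4652 (MRI 72 hpi against mock), 0 (MRI 48 against 24 hpi), 1356 (SB22 12 hpi against mock), 97 (SB22 48 against 24 hpi) and 3578 (SB22 72 against 48 hpi). A tested fold of at least 1.5, stricter by construction, gave in MRI 4214, 4326 and 4024 for 24, 48 and 72 hpi against mock, 2879 for 24 against 12 hpi, 0 for 48 against 24 hpi and 433 for 72 against 48 hpi. In SB22 it gave 39, 6260, 9864 and 10373 for 12, 24, 48 and 72 hpi against mock, then 5704, 13 and 6361 for the 3 steps. Removal of mock-undetected features left 31 for MRI 12 hpi against mock, 993 for SB22 48 against 24 hpi and 7808 for SB22 72 against 48 hpi. Thinning moved only MRI 48 against 24 hpi, to 0. Apart from the stricter fold, which tests for a larger change, the cause was not tested.

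Leaving out 1 replicate gave these ranges. In MRI they were 25 to 213 (12 hpi against mock), 6353 to 9069 (24 hpi), 6662 to 8571 (48 hpi), 5939 to 9741 (72 hpi), 4710 to 5891 (24 against 12 hpi), 0 to 320 (48 against 24 hpi) and 724 to 4643 (72 against 48 hpi). In SB22 they were 58 to 108, 9893 to 10881, 12995 to 15978, 14413 to 15243, 9713 to 10181, 62 to 462 and 5574 to 11307 in the same order. With 2 libraries left in a group, the fits have less power. The 8 named features kept their direction and their call in every fit that tested them. The 4 rising ones were not tested in the fit without mock-undetected features, nor the 2 of MRI among them in the fit of the 2 groups alone. The groups of each cultivar still differed in the share of the 100 most abundant features without any 1 library, a check added after seeing the data.

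The share of SB22 from 12 to 72 hpi kept its direction and threshold under all alternatives, from a log2 of 2.25 with TPM to 5.19 without 12 hpi replicate 2 and 3.95 without 72 hpi replicate 3. That of MRI changed sign with TPM (0.17), with features counted in all 3 libraries of a time (0.068) and without 12 hpi replicate 1, 72 hpi replicate 2 or 3 (0.40, 0.00 and 0.29; range -0.42 to 0.40), never past the threshold. The cultivar difference was 0.51 with TPM (exact permutation test, p = 0.0958) and 0.92 to 1.46 without a replicate number. With TPM the mean share was 2.01% in MRI mock and 2.62% to 2.72% in its inoculated groups. In SB22 it was 1.23% in mock, 2.16% at 12 hpi and 10.5% at 72 hpi. TPM gives short features with few counts more weight by construction.

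With the replicate block, the count for MRI 48 against 24 hpi, taken as paired, went from 2 to 1. The block was fitted over all 15 libraries of a cultivar, so it was no paired fit of that contrast alone. No other count moved by 1.5 times. SB22 12 hpi against mock gave 254, SB22 48 against 24 hpi 686 and MRI 12 hpi against mock 417. The block left the SB22 share past the threshold (exact permutation test, p = 0.00231) and the MRI share not (p = 0.958, exact). Elsewhere replicates were taken to share only a number. Yet every library of the first-named group correlated best with its own number in SB22 12 hpi against mock, 72 hpi against mock and 24 against 12 hpi. In MRI 48 against 24 hpi this did not hold for every library, so which libraries are paired stays uncertain. Depth limits what mock can show: a feature at 0 in a mock library of 6504048 counts may hold up to 3 counts. Of simulated 2-fold changes, 35% to 38% were recovered, but these were set in well-covered features only. The recovery over all tested features, low-count ones included, was not measured.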

Other observations

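The features gained and lost at equal depth, their levels and the ratio tests were chosen after the data were seen, as was the test of single libraries, except that the prediction for the same-sign test was written before its result. With the libraries of each cultivar thinned to its smallest total, features with no count in the 3 mock libraries and at least 5 in all 3 libraries of a time numbered 781, 430, 142 and 462 at 12, 24, 48 and 72 hpi in MRI, and 282, 1006, 741 and 3985 in SB22. The converse, features lost, numbered 0, 41, 45 and 17 in MRI and 1, 60, 81 and 24 in SB22. The 781 features gained at 12 hpi in MRI together held 1918 CPM ± 643 at 12 hpi, 1078 ± 255 at 24 hpi, 334 ± 177 at 48 hpi and 1308 ± 1291 at 72 hpi, where the libraries ranged from 186 to 2719 (SD, n = 3 each). The 282 of SB22 held 608 CPM ± 158, 994 ± 358, 2475 ± 2324 and 21097 ± 18311 at those times. As the features were picked at 12 hpi, their value at that time is biased upward.

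In MRI, nearly all features called at 12 hpi against mock were higher. Shallow mock libraries do not account for it, with 781 features gained and 0 lost at equal depth. Nor does any 1 library account for the direction, since at least 85.4% of the calls were higher without any one of the 6, though their number, 319 with all, was then 25 to 213. Whether the gained features moved together, as a single added source of RNA would require, was not decided: the log2 ratio had an interquartile range no wider than over features detected in mock in 0 of 3 pairs of MRI 72 hpi libraries (0.74, 1.35 and 1.69 over the 559, 440 and 213 features with enough counts, against 0.56, 0.52 and 0.69), but low counts widen it (0.93, 0.97 and 1.06 over features detected in mock with low counts). RNA of sprayed sporangia and a response of leaf genes both stay open.

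In both cultivars the mock and 12 hpi libraries lay on one side of those of 24, 48 and 72 hpi along the first principal component. For the counts of changed features, depth does not account for this pattern. With all libraries of a cultivar thinned to 1 total, 24 hpi against mock called 7720 features in MRI and 11045 in SB22. There 12 hpi against mock called 333 and 349. The step from 12 to 24 hpi kept at least 81.0% of its count after thinning (5793 in MRI and 9267 in SB22). This step could not test the depth of mock, as it holds no mock library and its groups had like depth. The components were not recomputed after thinning. If all plants were sprayed at 1 time of day, mock and 12 hpi leaves were taken 12 hours off the clock of the others. Of the features called from 12 to 24 hpi, 98.6% in MRI and 95.7% in SB22 had the same sign from mock to 48 hpi, but this restates the pattern and does not bear on time of day at harvest. That cause cannot be told apart from a change between 12 and 24 hpi that then lasted, as no mock leaves of 24 hours or later are in the design. Time of day also leaves the 3474 features of MRI and the 12195 of SB22 from 48 to 72 hpi without account.

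Other splits of the 6 libraries of a contrast into 3 and 3 number 10 with the real one, too few for a share under 0.05. With fits of the 2 groups alone on the features of the 15-library fit, the real split was the 1 largest of 10 in all contrasts but one. Every other split mixes libraries of both groups, so a difference between the groups widens its spread and lowers its count. The features were also filtered on the real groups. Counts of the other splits are therefore not the level that chance alone would give. For 12, 24, 48 and 72 hpi against mock it gave 1101, 5533, 7601 and 3960 features in MRI (highest other split 0, 7, 0 and 0) and 2253, 14852, 14437 and 13309 in SB22 (highest other 0 each). For 24 against 12 hpi it gave 6022 in MRI and 11292 in SB22 (highest other 0 each), and for 72 against 48 hpi 3310 and 3530 (highest other 1 and 0). For 48 against 24 hpi SB22 gave 16 (highest other 0), whereas in MRI all 10 splits gave as many as the real 0, the highest other giving 301. That split set 24 hpi replicate 1 with 48 hpi replicates 1 and 3 against the rest. It was picked as the highest after the fact, and whether these samples hold a structure other than time was not tested. The 3 other splits that part all pairs of equal number gave 0, like the real one.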
